A study of Saccharolobus islandicus and Sulfolobus acidocaldarius with 31 samples.

How the data were processed

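Chromosome contacts and transcripts were measured in 2 thermoacidophilic archaea. Per the labels, contacts came from 3C-seq, in which crosslinked DNA is digested with AluI, ligated to its neighbours in space and sequenced as pairs. Transcripts came from strand-specific RNA-seq of total RNA. *Sulfolobus acidocaldarius* DSM639 gave 6 contact libraries and 2 RNA libraries, and *Saccharolobus islandicus* REY15A gave 12 contact libraries and 11 RNA libraries. The groups and replicate numbers were taken from the sample titles. Every contact group held 2 libraries. Each RNA group of *S. islandicus* held 2 libraries except the shaken parent on sucrose, which held 1, and the log-phase and stationary RNA of *S. acidocaldarius* held 1 library each. The labels do not say that libraries of a group came from separate cultures, so each p-value measures only the spread between these samples, which may be technical.

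The deposited contact counts were whole numbers per pair of bins with no normalisation, as the values themselves show, and pairs of a bin with itself were not listed. The bin size was not stated in the sources used here and was inferred: 1113 bins in *S. acidocaldarius* and 1262 in *S. islandicus* match the span of the gene coordinates at 2 kb per bin. The deposited balanced contact signal had the same total for every retained bin, and the submitters' processing notes name HiC-Pro 2.9.0 and Salmon 0.8.2 without giving their roles. The deposited estimated counts and TPM per gene stood in tables with the header of a Salmon quantification, per the file headers, and the authors' TPM covered all listed genes including rRNA. The aligner, its settings and the genome build of the contact maps are not given in the sources used here. Coordinates are those of the deposited gene tables, counted from 1. The tables give locus tags and do not pair them with gene names or products. None of the 2361 tags of *S. acidocaldarius* and 0 of the 2755 of *S. islandicus*, which include the 2 transgene entries, matched the gene table supplied for naming, which covers another *S. islandicus* strain, M.16.4. Gene lists that needed product names were therefore not used, and 6 of the 23 lists fixed beforehand had enough locus tags of their own to be described in *S. acidocaldarius*.

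Contact libraries held 12533894 to 27967688 contacts in *S. acidocaldarius* and 17308196 to 36434473 in *S. islandicus*, with a median of 12 to 40 contacts per pair of 2-kb bins. RNA libraries held 17179573 to 25740195 reads, of which 83.4% to 87.0% fell on 2 rRNA genes, leaving 2238503 to 4044045 reads on other genes. Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom between 1.56 and 41.6, so none was counted as a repeat deposit. Read and contact counts without molecular identifiers are not independent molecules, and a count of 0 by itself may be sampling error.

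Bins absent from any balanced matrix, or with under 25% of a library's median coverage, were left out in all libraries of that organism. Contacts were divided by the mean at the same circular distance. Compartments were the sign of the first principal component of the correlation matrix of these values in 30-kb segments, on the mean of the balanced matrices of a group, with A named as the side with higher mean log2(TPM + 1). Compartment strength was the mean log2 observed over expected contact within A and within B minus that between A and B, at distances of at least 60 kb. For strength and for counts of pairs, A and B were taken from log-phase *S. acidocaldarius* or from the shaken sucrose-grown parent of *S. islandicus*. Segments that leave these compartments lower a group's strength, so the group that gave A and B, and groups like it, are favoured. The insulation score of a 2-kb bin was the log2 mean balanced contact between the 20 kb on either side of it, over the chromosome's median, so that a low score marks a boundary. Boundaries were local minima with a prominence of at least 0.1 found within 1 bin of each other in both libraries. Contacts were also grouped by circular distance, with classes set at 10, 50 and 200 kb.

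RNA counts of *S. islandicus* were rounded and tested with the quasi-likelihood F test of edgeR 4.0.16 with TMM factors and its expression filter, in 1 model over all 11 libraries with a coefficient per group. Insulation scores were tested with limma 3.58.1, and raw contacts per pair of 30-kb segments with edgeR, in 1 model per organism over all its contact libraries. All were two-sided with Benjamini-Hochberg adjustment at 0.05. Where a group had 1 library it was assumed to vary like the other groups. The lacS and argD entries, listed only for the transgene strain, were tested in a model of that strain's libraries alone. Values with 1 number per library were compared with exact permutation tests. With 2 libraries against 2, the smallest p these allow is 0.333, so single comparisons of that kind cannot pass 0.05. Neighbouring bins and genes are not independent, so tracks along the chromosome were compared by exact circular shifts of one track against the other. The RNA of *S. acidocaldarius* has no replicate and is given as differences of log2(TPM + 1) with no p-value. Medians of gene lists there were placed among 10000 random lists of the same size matched on mean expression. Genes of compartment A were tested as a set with camera and fry of limma. Correlations over boundaries used 100000 permutations.

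The groups, tests, thresholds, named-gene rule and most alternatives were fixed before the data were examined. The rule named the engineered loci, then the genes with the largest rise and fall among those past the threshold that had a mean of at least 10 CPM and moved the same way in every pair of libraries. Because tags have no names here, at most 2 genes each way are printed per comparison. For *S. acidocaldarius* the rule took the largest differences among genes with at least 50 TPM in either library. For insulation and contact pairs it took the lowest adjusted p after merging called bins within 10 kb, and for boundaries the highest prominence. Alternatives covered DESeq2 1.42.0 as normalisation and as test, filters, only the groups compared, a replicate block, each library left out, other windows, segments, distances and prominences, raw in place of balanced contacts, operon in place of gene TPM, and other pseudocounts. Removing rRNA genes, the test of compartment A genes, a list of the 50 most expressed genes and the difference of arabinose effects on insulation were added after seeing the data.

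Tests were checked on simulated data before use. For the deletion against its control, edgeR recovered 77.3% of 1.5-fold, 92.5% of 2-fold and 98.5% of 4-fold changes among 2608 genes, with 6.81% of calls false. On the insulation scores of the stationary comparison, limma recovered 25.0% of changes of 0.1, 70.0% of 0.2 and 100% of 0.4 among 1113 bins, and in the deletion comparison 95.0% of changes of 0.1 and 100% of 0.2 among 1246 bins. For contact pairs, edgeR recovered 88.1% of 1.2-fold changes among 2701 pairs in the stationary comparison, with 9.64% of calls false, and 98.5% among 3486 pairs in the deletion comparison, with 2.72% false. Simulated maps gave back 100% of planted compartments and boundaries, and circular shifts of unrelated tracks gave a p under 0.05 in 3.80% of 500 draws. These maps had sampling noise only, less than real replicates, and all boundaries were planted at the same depth. Recovery of shallower boundaries was not tested. The simulated genes, bins and pairs were independent, few of them changed, all upward, and the groups shared 1 spread. Real changes went both ways and neighbours are not independent, so these rates of recovery and false calls may not hold for the real comparisons. The work used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.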

Results

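Contact maps and transcriptomes were collected from *Sulfolobus acidocaldarius* and *Saccharolobus islandicus* to describe how the chromosomes of these archaea fold and how the fold relates to transcription. *S. acidocaldarius* was sampled in log phase, 30 min after actinomycin D, and in stationary phase, with 2 contact libraries each and 1 RNA library each for log and stationary phase. *S. islandicus* was sampled as a parent strain lacking pyrEF and lacS, grown with sucrose or arabinose while shaken or with sucrose unshaken, as an slaAB deletion grown unshaken with sucrose, and as a strain carrying lacS and argD behind the ParaS promoter at SiRe_0163, grown shaken with either sugar. The genotypes of the last 2 strains also list a deletion of argD, which the parent lacks, with argD put back at the engineered site. Each of these 6 conditions had 2 contact libraries and 2 RNA libraries, except 1 RNA library for the shaken parent on sucrose. In *S. islandicus* the deletion libraries held 17308196 and 19327760 contacts, their control 19074406 and 21842861, and the arabinose-grown parent 34032794 and 36434473. In *S. acidocaldarius* the actinomycin D libraries held the fewest, 12533894 and 16604049, and the stationary libraries the most, 27967688 and 25269719.

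Both chromosomes were divided into an A and a B compartment in unperturbed cells, and A held the more expressed genes. In log-phase *S. acidocaldarius*, A covered 37 of 74 segments of 30 kb in 4 stretches of the coordinates, which run around a circle, from position 1 to 240000, 360001 to 810000, 1080001 to 1380000 and 2100001 to 2220000. In the shaken sucrose-grown *S. islandicus* parent, A covered 25 of 84 segments, an unbroken arc from 1080001 to 1800000 and the single segment from 120001 to 150000. The median gene was at 56.9 TPM in A and 20.9 in B in *S. acidocaldarius*, and at 63.1 and 23.8 in *S. islandicus*. Mean log2(TPM + 1) per segment was 5.98 ± 0.74 in A and 4.44 ± 0.92 in B (SD, over segments) in *S. acidocaldarius*, a difference of 1.54 that only the smallest share of circular shifts reached (exact circular-shift p = 0.0133 of 75 shifts, the smallest they can give). In *S. islandicus* it was 6.13 ± 0.75 and 4.55 ± 0.96, a difference of 1.58 (exact circular-shift p = 0.0118 of 85 shifts, the smallest they can give). Because A was named as the more expressed side, the sign of these differences is fixed and the two-sided test concerns their size. Segments of 1 chromosome are not independent replicates.

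**Figure D1:**
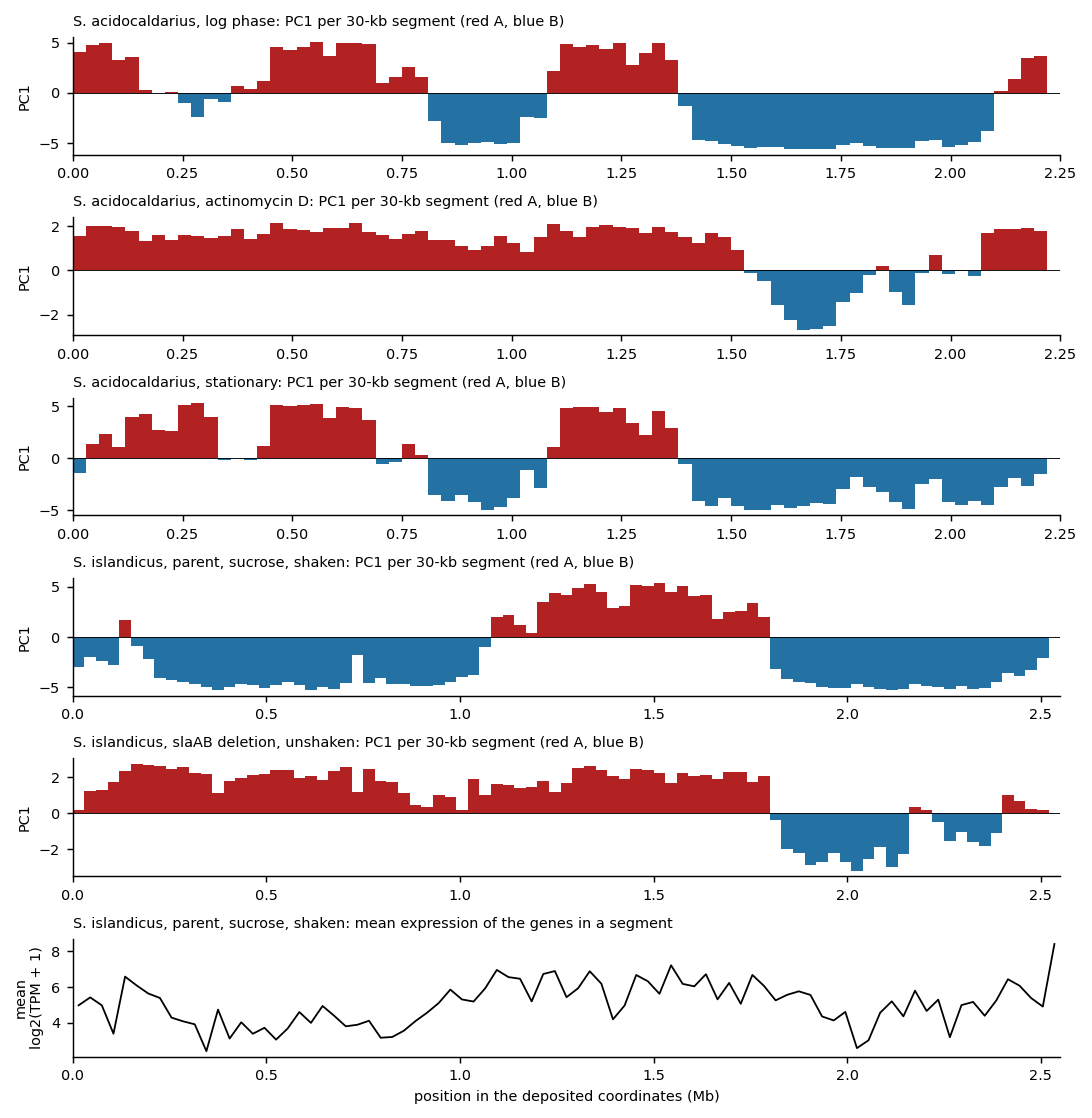
The first principal component (PC1) of the contact map per 30-kb segment is plotted along the chromosome, positive in A and negative in B, for 3 states of *S. acidocaldarius* and 2 of *S. islandicus*, above the mean log2(TPM + 1) of the shaken sucrose-grown *S. islandicus* parent. The arc of A from 1080001 to 1800000 in the parent gave way to a track with 66 of 84 segments on the positive side in the slaAB deletion. There the sign of PC1 rests on a correlation of only 0.0756 with expression.

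Local boundaries lay on average near more highly expressed genes in unperturbed cells of both species, though the most expressed gene near a boundary was at as little as 18.3 TPM in *S. acidocaldarius* and 28.4 TPM in *S. islandicus*. The most prominent boundary of log-phase *S. acidocaldarius* was at 462001 to 464000, next to Saci_0575 at 1173 TPM, with a prominence of 1.48. The boundary at 2196001 to 2198000 lay next to Saci_2355, listed beforehand as an S-layer gene and present at 5120 TPM. In *S. islandicus* the most prominent boundary lay on the rRNA gene SiRe_r0002 at 1036001 to 1038000, and the next at 1492001 to 1494000, beside the S-layer gene SiRe_1612. Among the 30 boundaries of log-phase *S. acidocaldarius*, the most expressed gene nearby was on average 1.06 higher in log2(TPM + 1) than at other bins (exact circular-shift p = 0.00359). For the 47 boundaries of the *S. islandicus* parent the difference was 1.01 (exact circular-shift p = 0.00238). With a prominence of 0.05, which admitted 63 boundaries, the *S. acidocaldarius* difference was 0.34 and no longer passed (exact circular-shift p = 0.151).

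Actinomycin D, a drug that blocks transcription by binding DNA, was used to ask whether the fold of the *S. acidocaldarius* chromosome depends on transcription. Because the drug binds DNA itself, an effect through transcription cannot be told apart here from a direct one. With A and B taken from log phase, treated cells had lower compartment strength and fewer contacts within B. Their maps had no minimum at the most prominent log-phase boundary. The treated map's own first component explained 71.0% of the correlation matrix, against 92.3% in log phase. Compartment strength was 0.0347 ± 0.0147 after the drug and 0.149 ± 0.0215 in log phase (SD, n = 2 each). Raw contacts between pairs of B segments fell in 508 of 632 pairs, while pairs of A segments rose in 280 of 633 and fell in 12. From balanced contacts, the mean log2 observed over expected went from 0.108 to -0.0280 within B and from 0.0341 to 0.0585 within A. At a minimum distance of 200 kb the balanced rise within A was only 0.00482, and the libraries of the states overlapped. The insulation score at 464001 to 466000 rose from -1.05 to 0.15, a change of 1.19 (SE 0.03, limma adjusted p = 3.85e-09), and at 2198001 to 2200000, which holds the listed S-layer gene Saci_2354, it rose from -0.57 to 0.23 (SE of the change 0.04, limma adjusted p = 2.30e-07). Raw coverage of treated over log-phase libraries was highest in the segment from 450001 to 480000, around the first of these bins, at a log2 ratio of 0.33. Its link to the lost minimum was not tested. The treated maps had 42 boundaries and the log-phase maps 30, with a median prominence of 0.300 and 0.291, and 9 of the 30 were found again at the same place (3.40 by circular shift). Contacts under 10 kb made up 23.5% ± 1.15 of all contacts after the drug and 13.9% ± 1.44 before it. No transcripts were measured after the drug, so A and B there were oriented with log-phase RNA, and the treated track put 58 of 74 segments in A.

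In tests across the whole map, 657 of 1113 bins changed their insulation score after actinomycin D, 315 higher and 342 lower (limma). Of 2701 pairs of segments, 1428 changed, 671 higher and 757 lower (edgeR). The pair with the lowest adjusted p among those that fell joined 960001 to 990000 with 1860001 to 1890000, both in B, at a log2 change of -0.66 (SE 0.04, edgeR adjusted p = 7.60e-08). The latter segment also had the largest loss of raw coverage after the drug, at a log2 ratio of -0.28. The pair test does not correct for the coverage of each segment. Both libraries of a state lay apart from both of the other for strength and for contacts under 10 kb, but the exact permutation p of 0.333 is the smallest that 2 against 2 allow, and over the 3 states together the exact permutation p was 0.2 for strength. The 2 treated libraries also differed most from each other, with a chi-square per degree of freedom of 41.6.

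Stationary phase asks whether the fold changes when growth stops. Stationary *S. acidocaldarius* also had lower compartment strength on the log-phase A and B, but a larger share of contacts at long distances. Its own first component explained 88.0% of the correlation matrix, against 92.3% in log phase. How much of the fall in strength came from moved segments was not tested. Uniform background ligation would also weaken compartments and raise the share at long distances. It was tested only for the slaAB deletion and remains open here. Replicate maps correlated at 0.637 over 10-kb pairs in stationary phase and at 0.814 in log phase. Compartment strength was 0.0423 ± 0.00383 (SD, n = 2), against 0.149 ± 0.0215 in log phase. Contacts under 10 kb made up 5.78% ± 0.0801 and contacts at 200 kb or more 70.3% ± 0.465, against 13.9% ± 1.44 and 62.4% ± 0.301 in log phase. Contacts between A and B rose in 393 of 1363 pairs and fell in 74, and contacts within B fell in 191 of 632 and rose in 10. The minimum at 464001 to 466000 was absent here too, with a score of 0.15 (change 1.19, SE 0.03, limma adjusted p = 3.61e-09), and the score at 2186001 to 2188000 rose from -0.33 to 0.25 (SE of the change 0.03, limma adjusted p = 7.61e-07). Raw coverage of log over stationary phase was lowest in the segment from 450001 to 480000, around that minimum, at a log2 ratio of -0.26. Log-phase coverage was thus low there against both other states. Whether the minimum arose from the log-phase libraries themselves was not tested. The stationary maps had 18 boundaries, and 5 of the 30 log-phase boundaries were found again (1.46 by circular shift).

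In stationary phase 593 of 1113 bins changed their insulation score, 266 higher and 327 lower (limma), and 819 of 2701 pairs changed, 486 higher and 333 lower (edgeR). Without stationary replicate 1 the counts were 359 bins and 323 pairs, without stationary replicate 2 they were 375 bins and 409 pairs, and offsets matched on distance gave 1368 pairs, 695 higher and 673 lower. The exact permutation p for strength was 0.333, the smallest possible, and both stationary libraries lay below both log-phase libraries. The stationary track had 32 of 74 segments in A, with 8 segments going from A to B and 3 from B to A. Mean log2(TPM + 1) differed by 0.76 between its A and B (exact circular-shift p = 0.0133, the smallest possible), with the stationary RNA library.

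**Figure D2:**
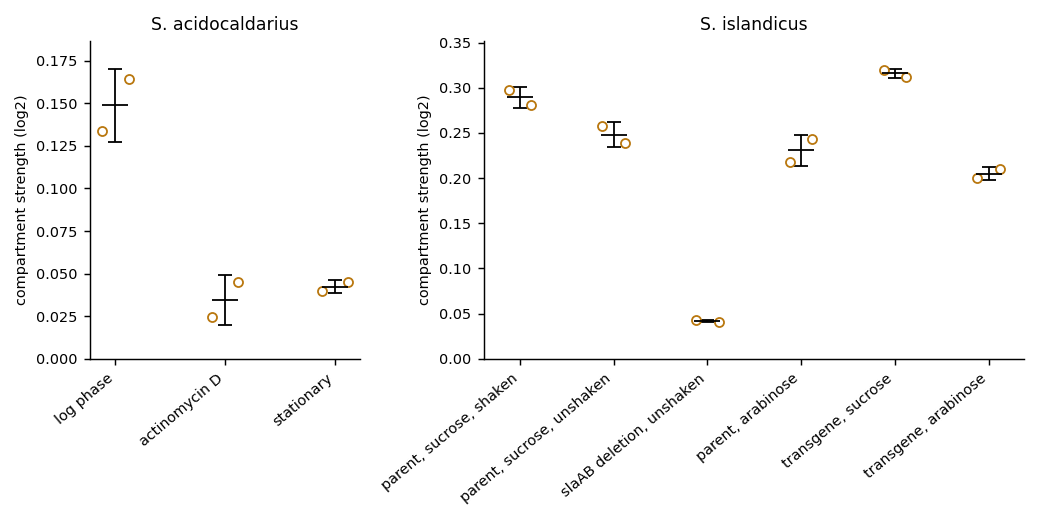
Compartment strength (log2) of each contact library is drawn as a circle, with the group mean and SD as bars, for the 3 states of *S. acidocaldarius* and the 6 conditions of *S. islandicus*. The lowest group mean in *S. islandicus* was that of the slaAB deletion, at 0.0416, and all log-phase *S. acidocaldarius* values lay above those after actinomycin D and in stationary phase.

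In stationary *S. acidocaldarius* part of the genes listed for motility and attachment had more transcripts than in log phase. The 17 measured genes of the archaella and pili list, which build the swimming filament and surface fibres, had a median difference of 1.29 in log2(TPM + 1), stationary minus log, with 11 members above 0 and 6 below. This lay above 99.9% of random lists matched on expression, but those lists are of single genes and ignore that the members lie in 3 groups of neighbours. All 5 genes from Saci_1493 to Saci_1497 lay below 0, between -0.07 and -0.59. Saci_1178 went from 55.0 to 349 TPM. Saci_2314 went from 84.5 to 395 TPM, whereas Saci_2319 went from 13407 to 7386 TPM. The 5 listed ESCRT cell division genes lay below 0 with a median of -0.86 (percentile 32.9 among random lists), the 3 listed chaperone genes at -1.16 (percentile 15.8), the 3 replication genes at -0.59 (percentile 15.5), the 3 chromatin genes at -0.65 (percentile 43.2) and the 2 S-layer genes at -0.10 (percentile 62.7), none of them outside the range of random lists in TPM. With CPM the percentile was 4.60 for the chaperone genes and 15.7 for the ESCRT genes. Saci_1322, listed as a chromatin protein, went from 13763 to 3696 TPM. Among 1260 genes with at least 50 TPM, 154 were at least 4-fold higher and 21 at least 4-fold lower, and the median difference was -0.22. The largest rise was Saci_1811, from 7.57 to 1407 TPM, followed by Saci_2095, from 3.09 to 352 TPM, and the largest falls in TPM were Saci_1255, from 204 to 18.7, and Saci_0868, from 244 to 32.0, a log2 difference of -2.89 that was -1.33 with CPM. Genes in log-phase A had a median difference of -0.28 and genes in B of 0.37. With 1 library per state these values describe 2 libraries and have no replicate check.

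**Figure D3:**
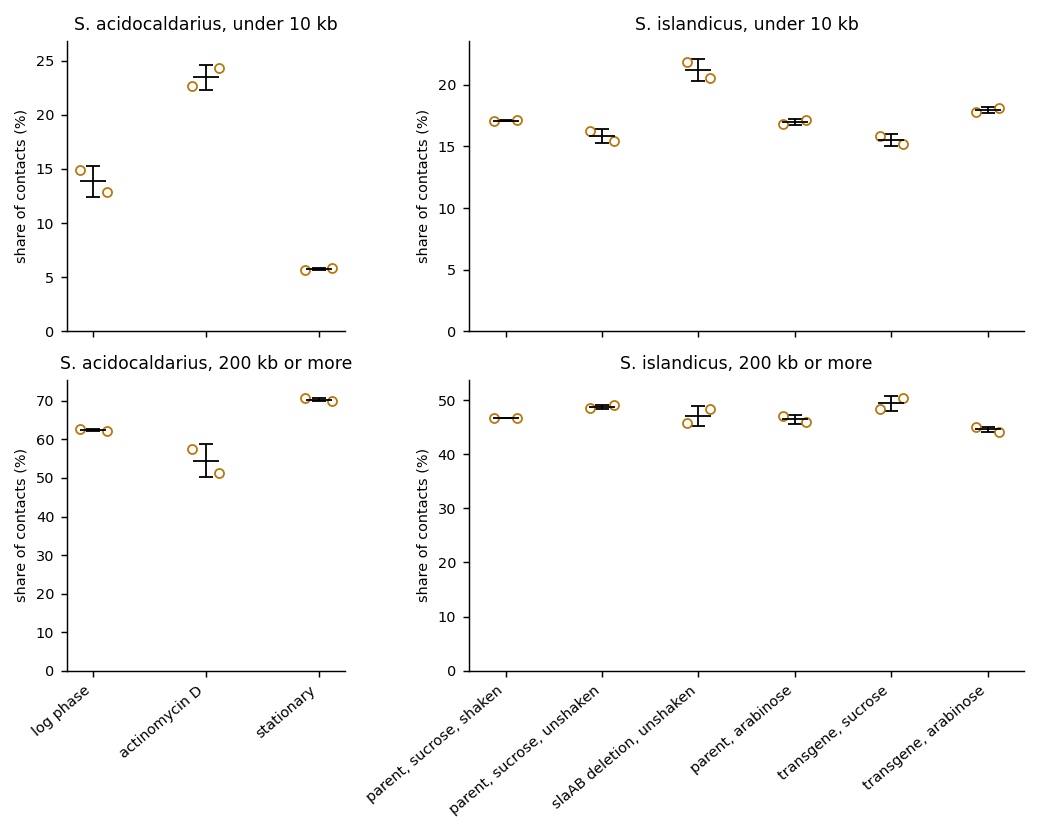
Each circle is the share of a library's contacts (in %) under 10 kb or at 200 kb or more, with group means and SD as bars. Short-range contacts were 23.5% after actinomycin D and 5.78% in stationary *S. acidocaldarius*, and 21.2% in the slaAB deletion of *S. islandicus* against 15.9% in its control.

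Loss of the S-layer, the protein lattice that encloses the cell, was studied by comparing an slaAB deletion with the parent, both grown without shaking, although the strains also differ in the site of argD. The engineered locus matched its label: SiRe_1612 at 1495096 to 1498785, listed beforehand as an S-layer gene, had 1 and 0 reads in the 2 deletion libraries and 459182 and 419447 in the control. Its neighbour SiRe_1611 at 1493860 to 1495053 had 1 and 0 reads against 54181 and 49796. SiRe_1614, also on the list fixed beforehand, had 297 and 311 reads against 409 and 375 and lay outside the emptied stretch. The deletion changed 1486 of 2623 genes tested, 770 higher and 716 lower, and 265 rose and 96 fell at least 2-fold (edgeR). The 2 deletion libraries differed more from each other than the control's, with a chi-square per degree of freedom of 29.5 against 3.79. The model estimates the spread from all groups together, so these p-values may understate the spread of the deletion. Groups of neighbouring genes rose together: 31 of 31 genes from 2009472 to 2050068 rose at least 2-fold with a median log2 change of 1.88, 12 of 12 from 600661 to 606327 with a median of 2.98, and 7 of 8 from 623184 to 629810 with a median of 4.46. The largest rises were SiRe_0655 at 627074 to 627526 by 5.25 (SE 0.50, edgeR adjusted p = 6.77e-06) and SiRe_0621 at 601240 to 601839 by 4.97 (SE 0.42, edgeR adjusted p = 2.79e-06), on the log2 scale.

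Apart from SiRe_1611 and SiRe_1612, the largest falls were SiRe_1463 at 1369626 to 1370030, with 0 reads in both deletion libraries against 4438 and 3820, and SiRe_1881 at 1739804 to 1740244, which fell by 3.14 on the log2 scale (SE 0.12, edgeR adjusted p = 1.43e-08). SiRe_1463 was also near 0 in the other strain whose genotype lists an argD deletion, with 0, 1, 10 and 3 reads in its libraries, so its loss may belong to the engineered genotype and is not ascribed to slaAB. The longest run of falls lay from 1903432 to 1923781, where 22 of 25 genes fell at least 2-fold with a median log2 change of -2.05. Contacts were missing in part of the same stretch: bins from 1908001 to 1924000 had 17.5% and 10.5% of the median coverage in the deletion libraries and 83.1% to 85.8% in the 10 other *S. islandicus* libraries. Genes of compartment A fell relative to genes of B, with a median log2 change of -0.20 over 884 genes in A and 0.16 over 1738 in B. In A, 150 genes rose and 371 fell, and in B 620 rose and 345 fell. This set test, chosen after seeing the data, gave p = 1.18e-08 with camera's preset correlation and p = 0.00785 with an estimated correlation. It was not particular to the deletion: arabinose in the transgene strain gave p = 0.0274 and arabinose in the parent p = 0.0583 with an estimated correlation, with medians of -0.06 in A and 0.08 in B, and of -0.04 and 0.06.

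The compartment pattern of *S. islandicus* was mostly lost in the deletion. Compartment strength was 0.0416 ± 0.00122 in the deletion and 0.248 ± 0.0140 in the control (SD, n = 2 each). Contacts between A and B rose in 1094 of 1471 pairs and fell in 93, and contacts within B fell in 816 of 1655 and rose in 51 (edgeR). Within A the direction depended on the correction: raw contacts fell in 142 of 277 pairs and rose in 32 (edgeR), whereas the mean balanced contact over that expected for the distance was 0.0595 in the deletion and 0.0442 in the control (log2). The main component of the deletion map explained 44.0% of the correlation matrix, against 88.8% in the control. It put 66 of 84 segments on the side named A. Expression no longer differed detectably between the sides of this component, by 0.22 in log2(TPM + 1) (exact circular-shift p = 0.659). The name A rests on a correlation of only 0.0756 with expression, although the component correlated at 0.464 with that of the shaken parent. The second component explained 26.5% in the deletion and 7.09% in the control, and was not compared with expression. Contacts under 10 kb made up 21.2% ± 0.882 in the deletion and 15.9% ± 0.577 in the control. Replicate maps of the deletion correlated at 0.667 over 10-kb pairs and those of the control at 0.886, and such pairs are not independent.

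At the deleted locus a low insulation score gave way to a high one. No boundary was called there in the control, although both of its libraries had low scores. The lowest bin of the locus was at 1498001 to 1500000 in replicate 1 (-0.376) and at 1492001 to 1494000 in replicate 2 (-0.429). A call needs minima within 1 bin of each other. The 2 bins inside the deleted genes were left out in all libraries because the deletion libraries had almost no contacts there, so the score describes contacts between their flanks. The insulation score at 1496001 to 1498000 went from -0.32 to 0.36, a change of 0.68 (SE 0.02, limma adjusted p = 2.02e-14). Farther out, scores went the other way, from 0.62 to 0.11 at 1476001 to 1478000 (SE of the change 0.01, limma adjusted p = 2.02e-14). The largest rise, of 1.12 at 1914001 to 1916000, lay within the stretch of missing coverage. In all, 1044 of 1246 bins changed, 599 higher and 445 lower (limma), and 2275 of 3486 pairs changed, 1208 higher and 1067 lower (edgeR). Expression at the 41 boundaries of the deletion exceeded that elsewhere by 0.22 (exact circular-shift p = 0.493), although a 40-kb window gave 13 boundaries with an excess of 1.64 (exact circular-shift p = 0.00555).

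**Figure D4:**
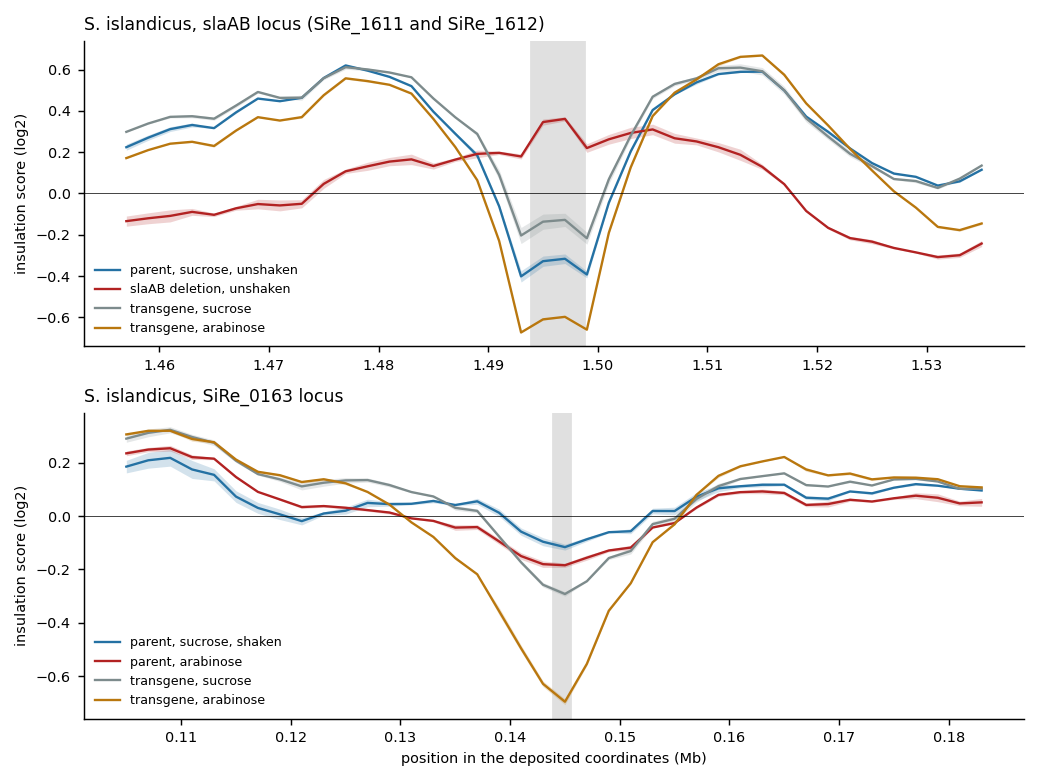
Insulation scores (log2, group mean with the range of 2 libraries shaded) are plotted by position around the slaAB locus and SiRe_0163, with the genes in grey. The dip at slaAB in the control, -0.32, was absent in the deletion, at 0.36, and the dip at SiRe_0163 was deepest in the transgene strain on arabinose, at -0.70.

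Arabinose in place of sucrose tests the response of the parent strain to the sugar later used to induce the transgene. It changed 135 of 2623 genes, 96 higher and 39 lower (edgeR), and 37 of the rises but 6 of the falls reached 2-fold. Some rises were in neighbouring genes, with 8 of 8 genes from 1293405 to 1302132 at a median log2 change of 2.35 and a further 8 among 12 genes from 1953362 to 1969615. SiRe_2125 at 1961642 to 1962763 rose by 3.66 (SE 0.11, edgeR adjusted p = 1.60e-08) and SiRe_1382 at 1301431 to 1302132 by 2.99 (SE 0.26, edgeR adjusted p = 2.68e-05). SiRe_2234 at 2080102 to 2082273 fell by 1.23 (SE 0.07, edgeR adjusted p = 9.49e-07) and SiRe_2243 at 2091724 to 2092824 fell by 1.14 (SE 0.07, edgeR adjusted p = 1.06e-06). The sucrose arm was 1 library, and without arabinose replicate 1 or replicate 2 the count was 72 or 81.

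In the contact maps of the parent, arabinose lowered contacts within B and raised those within A and between A and B. Contacts within B fell in 793 of 1655 pairs and rose in 17, contacts within A rose in 163 of 277, and contacts between A and B rose in 636 of 1471 and fell in 85 (edgeR), for 1694 changed pairs of 3486. The segments from 30001 to 180000 all had a positive PC1 on arabinose, with 4 segments changing from B to A. Some barely crossed: PC1 was 0.0198 at 90001 to 120000 and 0.0135 at 150001 to 180000, against 2.41 at 120001 to 150000. The segments at 30001 to 60000 and 60001 to 90000 had 0.453 and 0.496. In the transgene strain on arabinose, 150001 to 180000 was at -0.0439. For the counts of pairs and for strength, A and B came from the sucrose libraries compared here. Compartment strength was 0.231 ± 0.0173 on arabinose and 0.289 ± 0.0116 on sucrose (SD, n = 2 each, exact permutation p = 0.333, the smallest possible). Insulation at the slaAB locus deepened, with the score between its flanks at 1496001 to 1498000 going from -0.29 to -0.52 (change -0.23, SE 0.02, limma adjusted p = 1.35e-07). SiRe_1612 itself differed by 0.18 in log2 and did not pass the test (edgeR adjusted p = 0.255). Of 1246 bins, 703 changed, 405 higher and 298 lower (limma), but from raw contacts 442 changed, 160 higher and 282 lower, so that the balance of rises and falls depended on the matrix used.

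The transgene strain asks whether switching on transcription at 1 site changes the fold there. The lacS transgene, a sugar hydrolase used as reporter, rose 6.17-fold on arabinose, from 11849 and 8886 reads to 54296 and 56661 (log2 change 2.63, SE 0.05, edgeR adjusted p = 4.02e-15). The argD marker behind it rose by 0.32 (SE 0.08, edgeR adjusted p = 0.00781). Both values come from a model of the transgene strain's libraries alone. SiRe_0163, the insertion site, stayed between 25.8 and 39.0 TPM in all libraries. At 144001 to 146000 the insulation score of this strain went from -0.29 on sucrose to -0.70 on arabinose (change -0.40, SE 0.01, limma adjusted p = 2.46e-12), the lowest adjusted p among all falls of that comparison. In the parent the same bin went from -0.12 to -0.18 (change -0.07, SE 0.01, limma adjusted p = 0.000597). The score at the slaAB locus of the transgene strain also fell, from -0.13 to -0.60 at 1496001 to 1498000 (change -0.47, SE 0.02, limma adjusted p = 9.39e-12), while SiRe_1612 differed by 0.11 in log2 and did not pass the test (edgeR adjusted p = 0.263).

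Across the chromosome, arabinose changed 396 of 2623 genes in the transgene strain, 256 higher and 140 lower (edgeR). SiRe_2125 rose by 3.32 (SE 0.08) and SiRe_2129 by 2.77 (SE 0.16), and SiRe_2234 fell by 1.41 (SE 0.06) and SiRe_2239 by 1.39 (SE 0.09). A run of 7 genes from 2080102 to 2092824 fell with a median log2 change of -1.32. Genes called in both strains changed in the same direction, with 75 rising (9.37 for independent lists) and 26 falling (2.08 for independent lists). The fold changes correlated at 0.386 (Pearson) and 0.468 (Spearman) across genes, which are not independent replicates, and no libraries were shared. The count was 131 without arabinose replicate 1, 152 without arabinose replicate 2, 233 without sucrose replicate 1 and 135 without sucrose replicate 2, 248 with DESeq2 and 652 with only the groups compared.

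The contact maps of the transgene strain also had weaker compartments on arabinose, 0.205 ± 0.00723 against 0.316 ± 0.00537 (SD, n = 2 each, exact permutation p = 0.333, the smallest possible). Neighbouring segments gained contacts in 76 of 83 pairs, contacts between A and B rose in 464 of 1471 and fell in 107, and contacts within B fell in 982 of 1655 and rose in 282 (edgeR). In total 1979 of 3486 pairs changed, and 612 of 1246 bins changed their insulation score, 295 higher and 317 lower (limma), against 468 higher and 234 lower from raw contacts. The bins called in both strains numbered 463 (345 for independent lists), of which 458 had the same sign, and insulation changes correlated at 0.826 across bins, which are not independent.

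**Figure D5:**
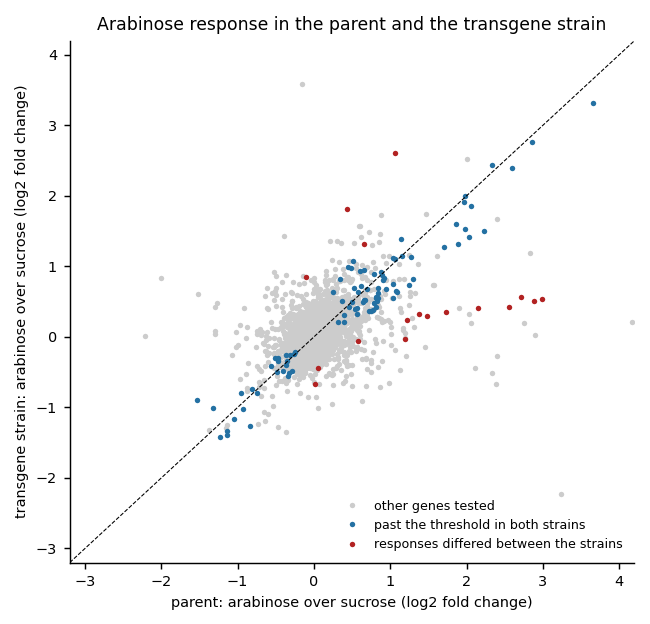
Each point is a gene, with its log2 fold change on arabinose in the parent (horizontal) and in the transgene strain (vertical). Of 2623 genes, 7 lie outside the axes, and 17 in red had responses that differed between the strains.

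On arabinose the transgene strain and the parent differed in 22 of 2623 genes, 12 higher and 10 lower (edgeR). SiRe_1027 at 983820 to 984917 was higher by 2.41 (SE 0.08, edgeR adjusted p = 1.48e-08) and its neighbour SiRe_1026 by 1.35 (SE 0.12, edgeR adjusted p = 0.000136). SiRe_1463 had 10 and 3 reads against 2977 and 2832, and SiRe_2654 at 2484838 to 2485269 had 89 and 41 against 5772 and 5022. On sucrose SiRe_2654 had 72 and 51 reads in the transgene strain and 4140 in the parent, so both losses may belong to the genotype of the strain and are not ascribed to arabinose. The count was 11 without parent replicate 1 or 2, 12 without transgene replicate 1, 9 without transgene replicate 2, and 317 with only the groups compared.

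Growth without shaking, the condition of the deletion's control, changed 72 of 2623 genes in the parent, 33 higher and 39 lower (edgeR). SiRe_1516 at 1414877 to 1415833 fell by 3.68 (SE 0.07, edgeR adjusted p = 1.06e-10) and SiRe_0112 at 98785 to 99783 fell by 3.53 (SE 0.09, edgeR adjusted p = 1.22e-09), the latter within a run of 7 genes from 93939 to 99783 that fell with a median log2 change of -1.80. SiRe_2180 at 2013199 to 2015094 rose by 1.73 (SE 0.10, edgeR adjusted p = 2.70e-06) and SiRe_2125 by 1.64 (SE 0.11, edgeR adjusted p = 4.00e-06). The shaken arm was 1 library, and without unshaken replicate 1 the count was 29. Compartment strength was 0.248 ± 0.0140 unshaken and 0.289 ± 0.0116 shaken (SD, n = 2 each, exact permutation p = 0.333, the smallest possible). A and B came from the shaken libraries, and the assignment was the same in all 84 segments.

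In the same comparison 470 of 1246 bins changed their insulation score, 199 higher and 271 lower (limma), and 292 higher and 262 lower from raw contacts. The count of bins was 178 without shaken replicate 2 and 194 without unshaken replicate 2. Of 3486 pairs, 398 changed, 202 higher and 196 lower (edgeR), with contacts within B falling in 181 of 1655 pairs and rising in 17. The count of pairs was 214 without shaken replicate 1, 136 without shaken replicate 2 and 37 without unshaken replicate 2, and 245 with DESeq2.

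Over all 6 conditions of *S. islandicus*, compartment strength differed between groups (exact permutation p = 0.000192 over 10395 splits of the 12 libraries). Contacts within gene lists asked whether genes of a kind cluster in space. The archaella and pili genes of *S. acidocaldarius*, at distances of at least 50 kb, had a mean log2 observed over expected contact of -0.09 (exact circular-shift p = 0.746). The 50 most expressed genes, a list added after seeing the data, had -0.01 in *S. acidocaldarius* (exact circular-shift p = 0.256) and 0.00 in *S. islandicus* (exact circular-shift p = 0.194), and none of the 3 passed.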

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

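The test of the arabinose effects on insulation against each other was chosen after the results were seen, and that on transcripts was planned.

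The effect of arabinose differed between the transgene strain and the parent in 17 of 2623 genes, 4 with a higher and 13 with a lower effect in the transgene strain (edgeR interaction, 231 genes at an unadjusted p under 0.05). Of these, 7 neighbouring genes from 1294370 to 1302132 had a median difference of effects of -2.13 on the log2 scale. SiRe_1382 had -2.45 (SE 0.30, edgeR adjusted p = 0.00185) and SiRe_1380 had -2.14 (SE 0.16, edgeR adjusted p = 9.07e-05). The parent's sucrose arm held 1 library, and the count was 11 without parent arabinose replicate 1, without parent arabinose replicate 2 or without transgene arabinose replicate 1. No explanation of this difference was tested.

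The effect of arabinose on insulation differed between the strains in 135 of 1246 bins, 22 higher and 113 lower in the transgene strain (limma interaction). The lowest p lay in the bin from 144001 to 146000, at the SiRe_0163 insertion site, where the effects differed by -0.34 (SE 0.02, limma adjusted p = 9.49e-09). Both transgene libraries on arabinose, at -0.69 and -0.71, lay below both on sucrose, at -0.28 and -0.30, and the parent's libraries at this bin lay between -0.11 and -0.19. The strains already differed there on sucrose, by -0.18 (SE 0.01, limma adjusted p = 2.92e-07). At the slaAB locus, in the bin from 1496001 to 1498000, the effects differed by -0.24 (SE 0.03, limma adjusted p = 1.66e-05). Much of this lay in the sucrose-grown cells, where transgene minus parent was 0.16 (SE 0.02, limma adjusted p = 1.87e-05). On arabinose it was -0.08 (SE 0.02, limma adjusted p = 0.0166). The difference between strains was thus not confined to the insertion site, and no explanation of it was tested.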

How the results depend on the processing

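Leaving out rRNA genes, camera with an estimated correlation, fry and the list of the 50 most expressed genes were chosen after the data were seen. The difference of contacts within A changed sign with the setting: for the deletion it was 0.0153 from balanced and -0.0574 from raw contacts, for stationary phase -0.0222 and 0.0137, and for arabinose in the transgene strain -0.0288 and, at a minimum distance of 200 kb, 0.015. From raw contacts the balance of bins with higher and lower insulation also turned, for both arabinose comparisons and for unshaken growth. Compartment strength kept its direction in 56 alternatives and the 2 reference compartment tracks in 10, though exact tests of strength could not pass in single comparisons. The shares under 10 kb and at 200 kb or more kept theirs except for arabinose in the parent, where they went from -0.0852 to 0.0829 without arabinose replicate 1 and from -0.242 to 0.300 without arabinose replicate 2. Contacts within the list of the 50 most expressed genes changed sign in both species and passed in no setting. Named genes kept their side of the threshold in 302 of 312 alternatives, with 9 losing and 1 gaining a call, and insulation at the engineered loci in 68 of 72, with 2 losing and 2 gaining one.

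Leaving out single libraries gave 29 to 51 genes for unshaken growth, 72 to 81 for arabinose in the parent, 131 to 233 for arabinose in the transgene strain, 9 to 12 between the strains on arabinose and 11 to 14 for the difference of arabinose effects. It gave 359 to 806 bins and 323 to 886 pairs for stationary phase, and 178 to 392 bins and 37 to 297 pairs for unshaken growth. Such fits hold fewer samples and assume that a lone library varies like the other groups.

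For arabinose in the transgene strain DESeq2 gave 248 genes and a model of only the groups compared 652, and that model gave 317 genes between the strains on arabinose. Raw contacts gave 442 bins for arabinose in the parent. DESeq2 gave 245 pairs for unshaken growth, and offsets matched on distance 1368 for stationary phase. The cause was not tested. Segments of 60 kb gave 408 pairs for actinomycin D, 221 for stationary phase, 638 for the deletion, 520 and 619 for arabinose in the parent and the transgene strain, and 213 for unshaken growth, out of 666 or 861 pairs tested, fewer than at 30 kb, and a larger share of those tested was called in each comparison. A prominence of 0.05 gave an expression difference of 0.34 at log-phase *S. acidocaldarius* boundaries (exact circular-shift p = 0.151), and the cause was not tested. For the archaella and pili list, a pseudocount of 0.1 gave a median of 1.46, of 5 gave 0.86 and CPM 0.99, at percentiles from 99.5 to 99.9. Of 48 alternatives for the *S. acidocaldarius* lists, named genes and gene counts, 30 gave another value, with no replicate to set it against.

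A replicate block gave 1447, 338 and 19 genes for the deletion, for arabinose in the transgene strain and between the strains on arabinose. The labels do not establish a pairing, and matching replicate numbers correlated between -0.14 and 0.12 in RNA and between -0.36 and 0.62 in contacts. With the block, counts of bins and pairs stayed within 1.5 times in all 6 contact comparisons. The minimum count for pairs left out no pair, so its removal says nothing. Contacts of a bin with itself, the RNA gene lists that needed product names, and boundaries without a replicate, which by definition need both libraries, were not run.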

Other observations

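The tests of background ligation, balancing, repeated sequence, loss in the contact libraries alone, coverage at replication genes and compartment A genes were chosen after the results were seen.

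Compartments were weaker in the slaAB deletion than in its control. Uniform background ligation strong enough to lower the control to the deletion's strength would put 75.3% to 75.6% of contacts at 200 kb or more, whereas the deletion libraries had 45.7% and 48.3%. Fewer contacts were argued against by control libraries thinned to the smaller deletion library, whose lower strength was 0.234, and balancing by raw counts, from which the higher deletion strength was 0.0438. The biological explanation that loss of the S-layer or the many changed transcripts altered the fold may hold, but it was not tested apart from other differences of this strain. These include a stretch of 16 kb with missing contacts and the low reads of SiRe_1463.

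The insulation score at the slaAB locus rose in the deletion. Removing 4.926 kb brings the flanks together, and the control's decay of contacts with distance gave an expected rise of 0.48 for this. The observed rises in 2 bins were 0.67 (SE 0.02) and 0.68 (SE 0.02), so under this setting the shorter distance could give much of the rise but less than was seen. The setting leaves out argD, put back at the engineered site, which would make the shortening smaller. It also takes the control's decay, although contacts under 10 kb made up 21.2% in the deletion and 15.9% in the control. The part of the rise due to distance is therefore uncertain. Loss of the transcription of SiRe_1611 and SiRe_1612 is a further explanation that was not tested.

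Contacts were missing from 1908001 to 1924000 in the deletion strain. Repeated sequence dropped in mapping would lower coverage in other libraries too, whereas the lowest of the 10 others had 83.1% of the median bin. A loss in the contact libraries alone would leave transcripts as they were, whereas the 21 genes there had a median log2 change of -2.07. A candidate explanation is a deletion carried by most cells of this culture, in line with the 17.5% and 10.5% of the median coverage that remained, and it was not tested further.

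Over the 30 log-phase boundaries of *S. acidocaldarius*, the change of insulation in stationary phase and the change of the most expressed gene nearby had a Spearman correlation of -0.13 (permutation p = 0.483). The bound fixed in advance counted any such p against the hypothesis that insulation weakened more where transcription fell. That bound was too strict, because the sign was the predicted one and 30 boundaries with 1 RNA library per state leave a weak relation open. Over the 45 control boundaries of *S. islandicus* the Spearman correlation for the slaAB deletion was 0.20 (permutation p = 0.176), with the sign opposite to the prediction. The Pearson correlation was -0.13 (permutation p = 0.378), with the predicted sign. The sign thus depended on the coefficient, and this test does not decide the question. Boundaries are not independent replicates.

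The hypothesis that raw coverage of log over stationary phase was higher near the 3 replication genes listed beforehand gave an exact circular-shift p of 0.149, and 3 genes are too few to decide it. The hypothesis that genes in compartment A fell relative to B in the slaAB deletion passed (camera p = 0.00785 with an estimated correlation, medians of -0.20 and 0.16 on the log2 scale), but so did arabinose in the transgene strain (camera p = 0.0274 with an estimated correlation). It was found and tested on the same data.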
